A study of Mus musculus with 10 samples.

How the data were processed

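Polyadenylated RNA was sequenced from 10 mouse melanoma tumours, 6 of the genotype BrafCA;Cdkn2af/f with Arf6Q67L and 4 of BrafCA;Cdkn2af/f without it. RNA was extracted with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. The file used is 1 table of raw counts per gene as deposited by the authors, with 52636 mouse Ensembl gene identifiers in rows and 1 column per library. STAR 2.5.2b, featureCounts 1.5.1, DESeq2 1.18.0 and the build GRCm38 are named in the submitters' processing notes, without the role of each. The strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Each column carries the library identifier of 1 sample's labels, so that all 10 columns were mapped and 0 were left over. Library numbers ran from 1 to 6 in Arf6Q67L tumours and from 9 to 12 in controls, so library order and genotype cannot be told apart. Symbols were found for 52403 identifiers (99.6%) in a GENCODE annotation of GRCm38, from which coordinates were also taken. Groups were taken from the genotype label, and tumours are numbered within a group in accession order, so the numbers pair no tumours.

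Total counts lay between 28635414 and 40869091 per library. A count of 0 allows up to 3 counts of a library's total, which is between 0.0734 and 0.105 CPM, the count scaled to library size. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. In every pair of tumours of 1 group, counts differed by far more than sampling noise (chi-square per gene of at least 77.9), so no library was counted as a repeat of another. P-values of the tests on single genes and on list scores measure the spread between these tumours. Those of the list test camera with a preset correlation do not, since they treat a list's genes as nearly independent. The labels give each tumour its own opening number in the title but do not say whether that number marks an animal, and they give no litter, sex or batch.

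Genes were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 (17286 genes kept), TMM factors, estimateDisp, glmQLFit with the robust option and glmQLFTest with genotype as the term, Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Fold changes are Arf6Q67L over control on the log2 scale, with a standard error (SE) equal to the fold change over the root of the F statistic. CPM values use the TMM factors, and log2 CPM values use a prior count of 2. The common biological coefficient of variation was 0.416.

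A set of 45 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which compares a list's genes with all others, with adjustment over the 45 lists. Camera was repeated with the correlation estimated from the data, and fry was run, directional and for mixed signs, which tests whether a list's genes move without comparing them with other genes. A list score was the mean log2 CPM of its tested members in a tumour. Scores and single genes were compared with a two-sided exact permutation test over all 210 splits of the tumours into 6 and 4, whose smallest possible p is 0.00476. Members past the threshold were counted over all genes tested and adjusted over the list alone.

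How many members to name in each list, within the limit of 4, was settled after values were seen, and some lists have none named. The result for 1 gene is not reported here. The text names Arf6, Braf and Cdkn2a; the 10 genes that rose and the 10 that fell most among those past the threshold, at a mean log2 CPM of at least 1 and with separate groups, leaving out predicted genes, pseudogenes and receptor segments; where none passed, the 5 of lowest unadjusted p in each direction; up to 4 members of lowest unadjusted p in each list described; Xist, Ddx3y, Eif2s3y, Kdm5d and Uty; and the gene with most counts in each library. H2-K1, Stat2, Irf9, Cd8a, Cd274, Col6a2 and the pigment genes Tyr, Dct, Tyrp1, Mlana, Pmel, Sox10 and Mitf were chosen after their values were seen.

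The edgeR step was tested on simulated data for the comparison of 6 tumours with 4, over 17286 genes. It recovered 42% of 100 genes changed by a fold of 2 and 81% of 100 genes changed by a fold of 4, with 2 false calls. DESeq2 1.42.0 recovered 66% and 92% of the same genes, with 51 false calls. A simulated list of 20 genes lowered by a fold of 2 passed camera with either correlation. With the preset correlation 0 of 45 other lists did. Genes were simulated independently of each other, with dispersions moderated across genes, so the shares recovered need not hold for these tumours. Nor does the simulated list test the preset correlation on lists whose members move together. In the tumours the correlation within the type I interferon list was estimated at 0.649.

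The alternatives were DESeq2, limma-voom with quality weights, the classic exact test of edgeR, a minimum fold of 1.5, RLE, upper-quartile and no normalization factors, no low-count filter and a stricter one (CPM of at least 1 in at least 4 tumours), sex as read from the counts, 1 surrogate variable (sva 3.50.0), runs of neighbouring title numbers as a random block, and each tumour left out in turn. For lists they also included leaving out shared members, and for scores a prior count of 0.5 and z-scores. A T cell score term, a skeletal muscle score term, the male tumours alone and, for lists, a sex or surrogate variable term were added after the data were seen. Genes of near-identical sequence, such as Ifit3 and Ifit3b, the H2 class I genes and Tpsb2 and Tpsab1, can share reads and their single values are uncertain. Reads of the Arf6Q67L transgene add to Arf6 only where its sequence matches the annotated gene.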

Results

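The data were gene counts from melanoma tumours of mice that carry BrafCA, a Cre-activated oncogenic Braf allele, and floxed Cdkn2a, a tumour suppressor locus. In 6 tumours the genotype also held Arf6Q67L, a form of the small GTPase ARF6 that is locked in its active state, and the other 4 tumours served as controls. Library totals lay between 31372896 and 37918116 counts in the Arf6Q67L tumours and between 28635414 and 40869091 in the controls. Spp1, which encodes the secreted matrix protein osteopontin, took the largest share of counts in every library, from 1.24% to 3.0%. Pearson's r of log2 CPM between tumours, computed across genes, which are not independent replicates, ran from 0.906 to 0.968. The first principal component held 25.8% of the variance and placed control 4 farthest from the other tumours.

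The series asks how tumours with active ARF6 differ in expression from tumours without it. The engineered genes were examined first. Arf6 (chromosome 12, 69372150 to 69373783, GRCm38) was measured at 104 ± 21.3 CPM (SD, n = 6) in Arf6Q67L tumours and 93.0 ± 17.4 CPM (SD, n = 4) in controls. Its log2 fold change was 0.17 (SE 0.18) with an edgeR adjusted p of 0.758, so the difference was smaller than the spread between tumours. The counts therefore do not tell the genotypes apart by the level of Arf6, and they hold no information on the base change itself. Braf (chromosome 6, 39603237 to 39725463) stood at 46.7 ± 3.17 CPM (SD, n = 6) and 41.4 ± 2.39 CPM (SD, n = 4), with an edgeR adjusted p of 0.442. Cdkn2a (chromosome 4, 89274471 to 89294653) stood at 11.9 ± 2.52 CPM (SD, n = 6) and 13.7 ± 5.32 CPM (SD, n = 4), with an edgeR adjusted p of 0.797 and no direction that held when control 3 was left out (log2 fold change 0.04).

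The 5 named genes of lowest p in each direction are given here, and several of those lower in Arf6Q67L tumours are interferon-stimulated. Mx1, an antiviral GTPase (chromosome 16, 97447035 to 97462907), stood at 13.5 ± 4.56 CPM (SD, n = 6) against 57.4 ± 15.7 CPM (SD, n = 4) in controls, a log2 fold change of -2.09 (SE 0.27). Ifit2 (-1.35, SE 0.19), Ifit3b (-2.01, SE 0.30) and Cmpk2 (-2.62, SE 0.40), which interferon also induces, and Pml (-0.51, SE 0.08), which encodes the scaffold of PML nuclear bodies, followed, each lower in 6 of 6 Arf6Q67L tumours than in any control. On the other side, Tes, which encodes a focal adhesion protein (chromosome 6, 17065149 to 17105828), stood at 307 ± 19.6 CPM (SD, n = 6) against 211 ± 10.97 CPM (SD, n = 4), a log2 fold change of 0.54 (SE 0.08). Gcsh of the glycine cleavage system (0.58, SE 0.10), Ttc12 (0.80, SE 0.15), Ric3, a chaperone of acetylcholine receptors (2.20, SE 0.42), and Tm7sf3 (0.39, SE 0.08) were also above every control in 6 of 6 tumours. None of these 10 genes passed the threshold in edgeR, where adjusted p-values ran from 0.146 for Mx1 to 0.233, and all 10 passed in DESeq2.

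In edgeR, 0 of 17286 genes were past the threshold in either direction, while 2023 genes (11.7%) had an unadjusted p under 0.05, of which 804 were higher and 1219 lower. DESeq2 called 158 genes higher and 251 lower, the classic exact test of edgeR 40 and 154, and limma-voom with quality weights 1 and 1. The groups did not overlap at all for 421 genes (2.44%), against an average of 0.952% by chance. How far this share varies between chance splits was not computed, so the excess is not a test.

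**Figure D1:**
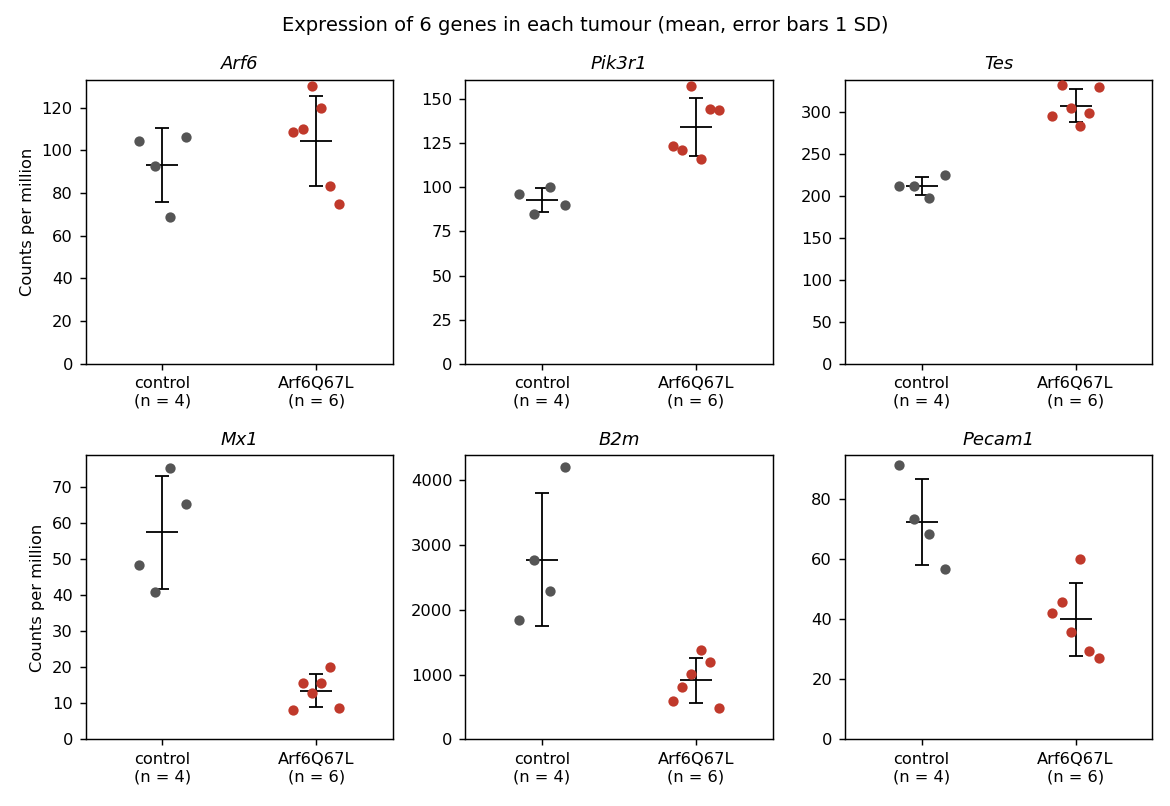
Expression of Arf6, Pik3r1, Tes, Mx1, B2m and Pecam1 in CPM (vertical axes, starting at 0) in the 4 control and 6 Arf6Q67L tumours, with 1 point per tumour, the mean as a horizontal line and error bars of 1 SD. The groups overlap for Arf6 and Pecam1, Mx1 and B2m are lower in 6 of 6 Arf6Q67L tumours than in any control, and Pik3r1 and Tes are higher.

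Genes of the type I interferon response were lower as a group. All 20 of 20 tested members had a negative log2 fold change, with a median of -1.71, so that the median member was 3.27 times as high in controls. Over all genes 0 members passed in edgeR, 20 did when adjusted over the list alone, and 17 passed in DESeq2. Isg15, a ubiquitin-like protein that interferon induces, stood at 14.01 ± 6.81 CPM (SD, n = 6) against 57.2 ± 12.5 CPM (SD, n = 4) in controls. The camera adjusted p was 2.62e-49 with the preset correlation, and adjusted p = 0.0896 with an estimated correlation. The list score was below all controls in 6 of 6 Arf6Q67L tumours (3.73 ± 0.68 against 5.64 ± 0.40, SD, n = 6 and n = 4, exact permutation p = 0.00476, the smallest the design allows, adjusted p = 0.214). Fry, directional, gave this list an adjusted p of 0.0190, the only list it called. Fry for members of mixed sign called 6 lists, those of angiogenesis (adjusted p = 0.00141), type I interferon (0.00409), pericytes (0.00985), endothelial markers, MHC class I and guidance genes (0.0423 for each of these). Stat2 (-1.26, SE 0.21) and Irf9 (-0.70, SE 0.20), which encode parts of the transcription factor that interferon receptors activate, had edgeR adjusted p-values of 0.199 and 0.283.

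Transcripts of the MHC class I list were lower too. All 17 tested members were negative, with a median log2 fold change of -1.79. In edgeR 0 passed over all genes and 17 passed when adjusted over the list alone. B2m, the invariant chain of every class I molecule (chromosome 2, 122147686 to 122153083), stood at 912 ± 349 CPM (SD, n = 6) against 2776 ± 1020 CPM (SD, n = 4). The heavy chains H2-D1 (-1.79, SE 0.38), H2-T22 (-1.68, SE 0.35), H2-Q4 (-2.33, SE 0.56) and H2-K1 (-1.91, SE 0.48) were below all controls in 6 of 6 tumours, with edgeR adjusted p-values from 0.233 to 0.248. Camera gave the list an adjusted p of 2.59e-29, and adjusted p = 0.289 with an estimated correlation. The interferon-gamma response list, which shares 4 members with the class I list, was negative in 23 of 23 members at a median of -2.002. Here 0 members passed over all genes, and 22 passed adjusted over the list alone. Nlrc5, the transactivator of class I genes (-2.11, SE 0.57), the peptide transporter Tap1 (-1.96, SE 0.52), the GTPase Irgm2 (-1.99, SE 0.55) and the proteasome subunit Psmb9 (-2.31, SE 0.65) had edgeR adjusted p-values from 0.273 to 0.283. Camera gave this list an adjusted p of 2.35e-25, and adjusted p = 0.315 with an estimated correlation. Cd274, which encodes PD-L1, was at 20.4 ± 10.2 CPM (SD, n = 6) against 63.3 ± 56.0 CPM (SD, n = 4), with an edgeR adjusted p of 0.345.

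Markers of T cells were lower with wide spread between tumours. The T cell list was negative in 18 of 19 members at a median of -1.73 (camera adjusted p = 8.97e-07, adjusted p = 0.686 with an estimated correlation) and of -1.10 without control 4, and 0 members passed in edgeR over all genes or adjusted over the list alone. Cd3e, a chain of the T cell receptor complex, was at 1.88 ± 1.99 CPM (SD, n = 6) against 10.6 ± 11.1 CPM (SD, n = 4), and among controls it ran from 1.20 CPM in control 3 to 23.8 CPM in control 4. Cd3g (-2.52, SE 1.02), Trac (-2.11, SE 0.90), Trbc2 (-1.40, SE 0.43) and Cd8a (-2.37, SE 1.06) had edgeR adjusted p-values from 0.304 to 0.425. The NK and cytotoxic list had a median of -1.14 (camera adjusted p = 0.0015, adjusted p = 0.686 with an estimated correlation), with Ccl5 at -3.03 (SE 1.08), Klrk1 at -2.23 (SE 0.83) and Ifng, which encodes interferon-gamma, at -2.75 (SE 1.09). The MHC class II list, a mark of antigen-presenting cells, had a median of -1.24 (camera adjusted p = 3.94e-04, adjusted p = 0.686 with an estimated correlation), with H2-DMb1 at -1.25 (SE 0.55) and H2-DMb2 at -1.15 (SE 0.53). Without control 4 the NK and cytotoxic list had a median of -0.64 (camera adjusted p = 0.0506) and the class II list of -0.61 (0.115). Compared by tumour, the T cell score had an exact permutation p of 0.138 (adjusted p = 0.478). That of the NK and cytotoxic score was 0.162 (adjusted p = 0.486) and that of the class II score 0.229 (adjusted p = 0.520).

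Inflammatory cytokines and chemokines were negative in 19 of 20 members at a median of -0.94 (camera adjusted p = 1.90e-06, adjusted p = 0.289 with an estimated correlation), which was -0.48 without control 1. Ccl3 (-3.32, SE 0.98), Ccl4 (-2.44, SE 0.92), Ccl5 and Tnf (-1.53, SE 0.57) had the lowest p-values, with 0 members past the threshold in edgeR. Macrophage markers had a median of -0.72 (camera adjusted p = 0.0148, adjusted p = 0.686 with an estimated correlation) and held members of both signs. The complement gene C1qb (-1.10, SE 0.42) and the Fc receptor Fcgr1 (-1.21, SE 0.40) were negative, while the phagocytic receptor Mertk (0.73, SE 0.21) and the scavenger receptor Cd163 (1.86, SE 0.68) were positive. The dendritic and Langerhans cell list had a median of -0.30 (camera adjusted p = 0.0233, adjusted p = 0.686 with an estimated correlation). The macrophage list was not past the threshold without Arf6Q67L tumour 6 (adjusted p = 0.294), control 2 (0.0513) or control 4 (0.213, median -0.28), and the dendritic list not without Arf6Q67L tumour 3 (0.109), Arf6Q67L tumour 5 (0.0611), control 2 (0.119) or control 4 (0.295). The dendritic median ran from -0.85 to -0.14 over the tumours left out.

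**Figure D2:**
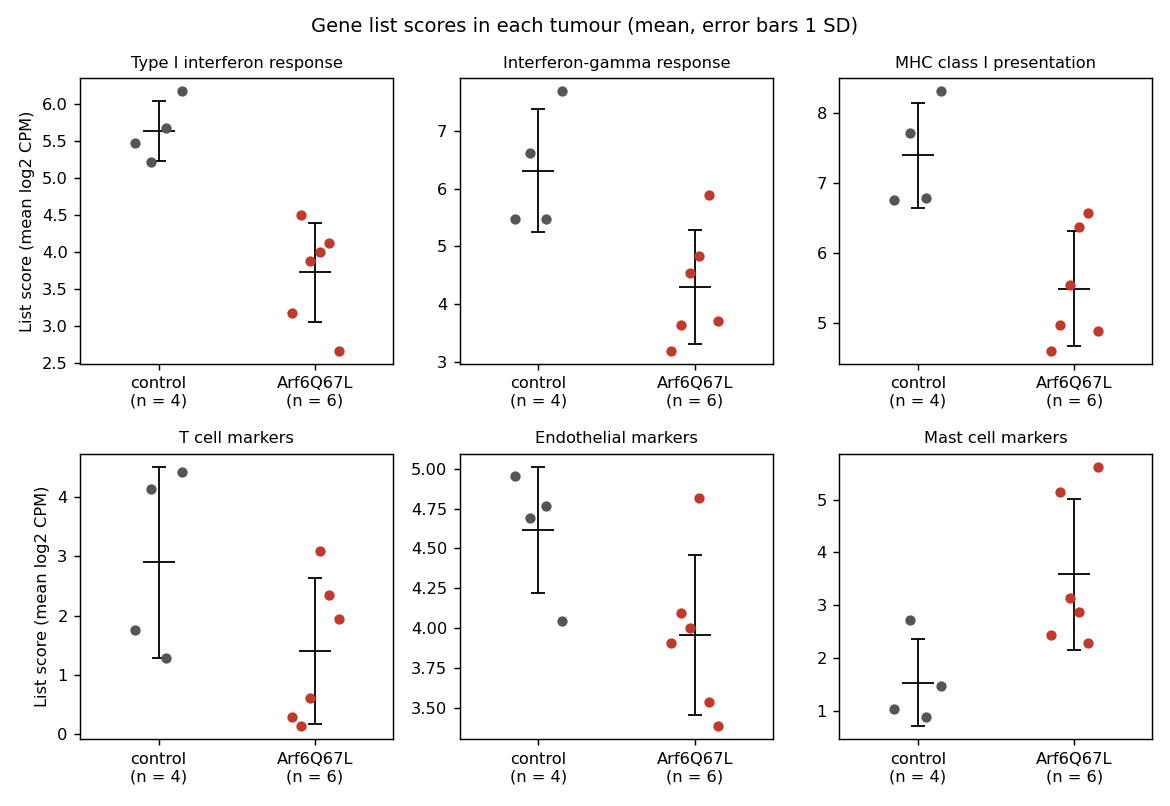
List scores, the mean log2 CPM of the tested members (vertical axes), in the 4 control and 6 Arf6Q67L tumours for 6 lists, with 1 point per tumour, the mean as a horizontal line and error bars of 1 SD. The type I interferon and MHC class I scores of 6 of 6 Arf6Q67L tumours lie below all controls, while the T cell and endothelial scores overlap and 4 of 6 mast cell scores lie above all controls.

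Lists of vessel genes had negative medians, with members of both signs. The blood and lymphatic endothelial list was negative in 11 of 16 members at a median of -0.57 (camera adjusted p = 1.16e-04, adjusted p = 0.577 with an estimated correlation), which was -0.35 without control 3. In edgeR 0 members passed over all genes and 3 adjusted over the list alone. Pecam1, an adhesion molecule of endothelial junctions, stood at 40.0 ± 12.2 CPM (SD, n = 6) against 72.4 ± 14.3 CPM (SD, n = 4), and Emcn (-1.20, SE 0.30), Robo4 (-1.01, SE 0.29) and Tie1 (-0.91, SE 0.33) followed. Angiogenic ligands and receptors had a median of -0.50 (camera adjusted p = 9.47e-04, adjusted p = 0.315 with an estimated correlation) and of -0.29 without control 1, and 0 members passed in edgeR over all genes and 3 adjusted over the list alone. Pdgfb (-0.93, SE 0.19) and the endothelial tip cell gene Esm1 (-2.42, SE 0.56) were below all controls in 6 of 6 tumours, and Angpt1 (-0.96, SE 0.26) in 5 of 6. The pericyte and smooth muscle list had a median of -0.72 (camera adjusted p = 0.0276, adjusted p = 0.662 with an estimated correlation), with Mylk at -1.29 (SE 0.33) and Acta2 at -1.55 (SE 0.45), and 2 members passed adjusted over the list alone. It was past the threshold neither without Arf6Q67L tumour 3 (adjusted p = 0.109), 5 (0.145) or 6 (0.0769) nor without control 3 (0.0655) or control 4 (0.161). With no low-count filter the pericyte list did not pass either (0.0949), at a median of -0.21.

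Mast cell markers were higher in Arf6Q67L tumours. All 10 members had a positive log2 fold change at a median of 3.03 (camera adjusted p = 9.89e-07, adjusted p = 0.577 with an estimated correlation), which was 1.89 without Arf6Q67L tumour 6 and 4.19 without control 2. In edgeR 0 members passed over all genes and 7 adjusted over the list alone, and 5 passed in DESeq2. Fcer1a, a chain of the IgE receptor (3.03, SE 0.80), was above all controls in 6 of 6 tumours, and the granule proteases Tpsb2 (3.44, SE 1.04), Tpsab1 (3.18, SE 1.16) and Mcpt4 (3.26, SE 1.14) were highest in Arf6Q67L tumours 2 and 6. Mcpt4 reached 112 and 152 CPM in these, against 14.4 CPM in the highest control. The mast cell score had an exact permutation p of 0.0429 (adjusted p = 0.321). Skeletal muscle markers had a median of 0.75 (camera adjusted p = 1.27e-04, adjusted p = 0.686 with an estimated correlation) and did not follow genotype tumour by tumour. The calcium pump Atp2a1 was at 118 CPM in Arf6Q67L tumour 5 and 2.63 CPM in tumour 1, and at 67.9 CPM in control 4 and 0.566 CPM in control 2. The release channel Ryr1 had a log2 fold change of 1.08 (SE 1.22). The list's median was 4.30 without control 4 and 0.13 without Arf6Q67L tumour 5.

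Of the pathways near ARF6, the PI3K-AKT component list was not past the threshold (median 0.13, camera adjusted p = 0.414), and 1 of its 27 members passed adjusted over the list alone. That member was Pik3r1, the regulatory subunit p85-alpha of PI3K (chromosome 13, 101680563 to 101768217), at 134 ± 16.5 CPM (SD, n = 6) against 92.8 ± 6.89 CPM (SD, n = 4), a log2 fold change of 0.53 (SE 0.11) with an adjusted p of 0.233 in edgeR and 0.00219 in DESeq2. Akt1 (0.25, SE 0.09) was also above all controls in 6 of 6 tumours (edgeR adjusted p = 0.364), and Pik3ap1 (-1.20, SE 0.46) and Pik3r5 (-0.91, SE 0.40) were negative. Endosomal recycling and exocytic machinery was positive in 21 of 27 members, with a median of 0.10 (camera adjusted p = 0.0233, adjusted p = 0.686 with an estimated correlation) and 0 members past the threshold adjusted over the list alone. Rab4a of the fast recycling route (0.67, SE 0.20), Rab11fip3 (0.32, SE 0.12) and the lipid kinase Pip5k1c (0.34, SE 0.13) were positive and Rab11fip4 (-1.70, SE 0.64) negative. That list was not past the threshold without Arf6Q67L tumour 1 (adjusted p = 0.0750), 2 (0.0589) or 3 (0.0533), or without control 3 (0.131), and its median ran from 0.0663 to 0.18 over the tumours left out. Nor did it pass with sex (camera adjusted p = 0.0690, median 0.0523), the surrogate variable (0.265), the T cell score (0.377) or the muscle score (0.0753) as a term, or in male tumours alone (0.0725). Exchange factors and GTPase-activating proteins of ARF6 had a median of -0.03 (camera adjusted p = 0.400), with Cyth4 (-0.90, SE 0.33), Asap3 (-0.57, SE 0.21) and Cyth1 (-0.28, SE 0.12) negative. The ARF GTPase list had a median of 0.03 (camera adjusted p = 0.907).

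The signalling and cell state lists given next were measured in bulk tumour tissue, which also holds other cells. None of them was past the threshold in camera. The RAF-MEK-ERK output list had a median of 0.13 (camera adjusted p = 0.494), with Fos at -1.50 (SE 0.47) and the ERK inhibitor Spred1 at 0.26 (SE 0.14). Epithelial-mesenchymal transition and invasion genes had a median of 0.06 (camera adjusted p = 0.884). Vim, an intermediate filament of mesenchymal cells, was at 4736 ± 769 CPM (SD, n = 6) against 3447 ± 553 CPM (SD, n = 4), Mmp14 had a log2 fold change of 0.38 (SE 0.17), and the repressors Snai2 (-0.60, SE 0.20) and Snai1 (-0.32, SE 0.14) were negative. mTORC1 and sterol synthesis targets had a median of 0.06 (camera adjusted p = 0.0746), with Fasn (0.35, SE 0.12) and Acaca (0.31, SE 0.13) positive. Melanocyte differentiation and pigmentation genes had a median of -0.12 over 10 tested members (camera adjusted p = 0.593), with Rab27a at -1.27 (SE 0.55) and Mlph at 0.51 (SE 0.48). Members under the expression filter, among them Tyr, Dct, Tyrp1, Mlana and Sox10, are not covered by that median. Cell cycle and proliferation had a median of 0.09 (camera adjusted p = 0.745) and neural crest-like and dedifferentiated melanoma of 0.08 (0.873). Medians were -0.04 for FOXO target genes (0.916), -0.18 for TGF-beta target genes (0.377), 0.08 for Wnt/beta-catenin target genes (0.536), 0.05 for integrin subunits (0.884), 0.01 for semaphorin, ephrin, slit and netrin guidance genes (0.873) and -0.21 for epithelial junctions (0.627), each with its camera adjusted p.

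**Figure D3:**
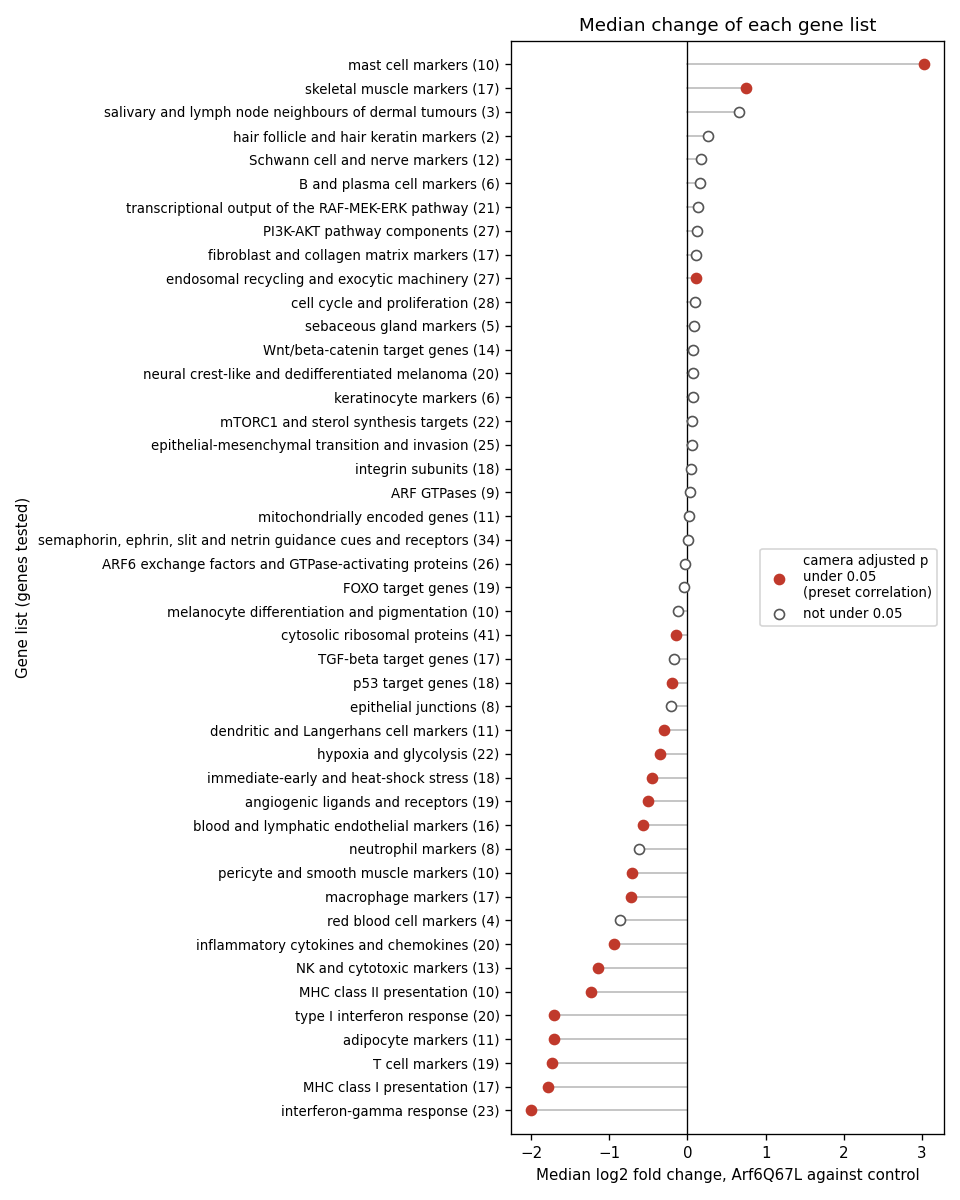
Median log2 fold change of Arf6Q67L against control (horizontal axis) for each of the 45 gene lists (vertical axis, with the number of genes tested), where filled points passed camera with the preset correlation. Interferon, MHC class I, T cell and adipocyte lists lie lowest, at medians from -2.002 to -1.71, and mast cell markers highest, at 3.03.

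Stress and tissue lists completed the set. Immediate-early and heat-shock genes had a median of -0.46 (camera adjusted p = 1.95e-04, adjusted p = 0.662 with an estimated correlation), which was -0.26 without control 4 and -0.73 without control 2, with Atf3 at -1.96 (SE 0.52) and Fos as given. Hypoxia and glycolysis genes were negative in 22 of 22 members at a median of -0.36 (camera adjusted p = 7.60e-04, adjusted p = 0.686 with an estimated correlation), with Higd1a at -0.41 (SE 0.13) and Pfkfb3 at -0.74 (SE 0.32), and without control 1 the median was -0.0494 (adjusted p = 0.530). Cytosolic ribosomal proteins had a median of -0.15 (camera adjusted p = 7.60e-04, adjusted p = 0.744 with an estimated correlation), which was -0.0891 without Arf6Q67L tumour 1. The p53 target list had a median of -0.19 (camera adjusted p = 0.0276, adjusted p = 0.686 with an estimated correlation) and was not past the threshold without Arf6Q67L tumour 2 (0.162) or 5 (0.0504), or without control 1 (0.119) or control 4 (0.161, median -0.0996). Adipocyte markers had a median of -1.71 (camera adjusted p = 0.0148, adjusted p = 0.722 with an estimated correlation), and -0.27 without control 4 (adjusted p = 0.907). Neutrophil (-0.62, camera adjusted p = 0.102), red blood cell (-0.86, 0.268), B and plasma cell (0.16, 0.873), fibroblast and collagen matrix (0.11, 0.826), keratinocyte (0.07, 0.873), hair follicle (0.26, 0.884), sebaceous gland (0.09, 0.873), Schwann cell and nerve (0.17, 0.907) and salivary and lymph node (0.66, 0.579) markers and mitochondrially encoded genes (0.02, 0.884) were not past the threshold. The last value is uncertain, since some mitochondrial genes had very low counts beside high ones and the settings of the counting are not known. Of the 45 lists, 17 were lower and 3 higher with the preset correlation and 0 passed with an estimated one. Median, mean and test differed in sign for 9 lists, those of PI3K-AKT components, invasion, ARF GTPases, FOXO targets, guidance genes, mitochondrial genes, B and plasma cells, keratinocytes and Schwann cells.

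Sex was read from Xist, which is expressed from the inactive X chromosome, and from Y-linked genes. By these, 3 of 6 Arf6Q67L tumours and 1 of 4 controls came from female mice. Xist was at 1190 CPM or above in those 4 and below 1 CPM (at most 0.975) in the other tumours. Ddx3y, Kdm5d and Uty were at or below 0.188 CPM in the female tumours and at 27.7 CPM or above in the male ones. With sex as a term edgeR again called 0 genes, and the type I interferon list kept its direction (camera adjusted p = 5.95e-46 with the preset correlation, while without that term the adjusted p was 0.0896 with an estimated one).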

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

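The tests of T cells, of sex, of normal skin (both) and of the most extreme list over all splits, given here, and the counts over splits for DESeq2, for unadjusted p-values and for lists, were chosen after the results in the real groups were seen, and those over all 210 splits after the drawn ones were seen. The count of genes past the threshold in edgeR over splits was planned.

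The first pattern is the lower type I interferon list. In every one of the 210 splits of the tumours into 6 and 4, the most extreme of the 45 lists was taken by its score difference over its standard error. In 8 splits, the real one included, some list was as far from 0 as this one (5.59 in the real split, at most 7.38 in another). That is 3.81% of the splits, so a chance split of the tumours is argued against only narrowly for this list. The splits treat the tumours as interchangeable, although no run of neighbouring title numbers held both genotypes. Genotype could thus be compared only between runs, and differences between runs that fall along genotype are not excluded. Fewer T cells are argued against as the whole cause, since with the T cell score as a term the score difference was -1.89 (95% interval -3.00 to -0.77) against -1.91 without it. The unequal shares of female and male mice are argued against as well, with a difference of -1.88 (95% interval -2.86 to -0.89) with sex as a term and -1.92 among the 3 and 3 male tumours. A lower interferon response within the tumour cells of the Arf6Q67L genotype may remain as a hypothesis, but other cell types that respond to interferon, litter and batch stay open and were not tested.

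The second pattern is the lower interferon-gamma response and MHC class I lists. By the same test over the 210 splits, some list was as far from 0 as the MHC class I list in 41 splits and as the interferon-gamma list in 96, so a chance split is not argued against for either. The same holds for other lists with negative medians, with 53 splits for inflammatory cytokines, 72 for angiogenesis, 171 for endothelial markers, 209 for each of T cell, NK and macrophage markers and 210 for pericytes. With the T cell score as a term, the difference in the mean of both scores was -1.17 (95% interval -2.19 to -0.16), against -1.96 without it. That interval excludes 0, which argues against fewer T cells as the whole cause, but the smaller size is consistent with T cells accounting for a part. A score from bulk tissue measures T cells with error, which a term in a fit cannot remove. Whether genotype acts on the tumour cells, on the infiltrate or on both was not tested.

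The third pattern is the mast cell markers. More normal skin with its epidermis in the Arf6Q67L samples is argued against as the whole cause, because the keratinocyte score difference (-0.46) lay below the mast cell one (2.05), a difference of -2.52 (SE 0.98, with 2 SE on each side reaching from -4.47 to -0.56). That score rests on 6 of 18 keratinocyte markers, whose median log2 fold change was 0.07, and some of the markers under the filter had more counts in Arf6Q67L tumours. With all 18 markers the difference from the mast cell score was -2.17 (SE 0.74), though many of them lie near the floor. Their summed CPM was highest in tumour 2 (240) and, of the Arf6Q67L tumours, lowest in tumour 6 (74.0), the tumours with most mast cell transcripts. That sum rests on the more abundant markers and does not show in which tumours those under the filter were higher. Adjacent tissue without epidermis was not tested and stays open. The skeletal muscle score was higher by 2.61, but not past the threshold (exact permutation p = 0.162, adjusted p = 0.486). The adipocyte (-0.66) and fibroblast (-0.00257) score differences were not positive. A chance split is not argued against, since in 120 of 210 splits some list was as far from 0 as this one. Mast cells that gather in the tumours may remain as a hypothesis beside it, resting mainly on Arf6Q67L tumours 2 and 6.

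Counts over the splits bear on the calls. For genes past the threshold in edgeR, all 100 of 100 splits gave at least the real count of 0, which any split must, so this shows nothing about chance. The highest other, 7 genes, came from the split that parts male from female tumours. For genes at an unadjusted p under 0.05, 4 of 100 drawn splits gave as many as the real 2023, with up to 2726 in another, which sampling of the splits leaves undecided. Over all 210 splits 10 did, just under 1 in 20, with up to 3396 in another, so chance is argued against only narrowly. For lists past the threshold with the preset correlation, 8 of 100 splits gave as many as the real 20, with up to 22 in another and a median of 13, and over all 210 splits 11 did, so chance is not excluded for that number. For genes called by DESeq2, 2 of 40 splits gave as many as the real 409, with 420 in the other, a share that does not exclude chance.

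A single tumour stood far from the rest of its group in 13 of 286 groups of values examined. Distance was the gap to the nearest other tumour as a share of the group's range. The cut-off flags about 1 in 20 groups of independent values. Many groups here are genes named for low p or lists that hold them, so the number is not a test of chance. Of the 13, 5 are the sex-linked genes in controls, where control 1 is the single female. There Xist was high (share 0.836), and Ddx3y (0.943), Eif2s3y (0.984), Kdm5d (0.982) and Uty (0.962) were low. Among controls, Cd163 was high in control 1 (0.920), Stat2 was high in control 4 (0.848), and the RAF-MEK-ERK output score was low in control 2 (0.920). Among Arf6Q67L tumours, Trbc2 was low in tumour 3 (0.673), Itgb4 was low in tumour 5 (0.771), Sema3d was high (0.634) and Slit2 low (0.669) in tumour 6, and the guidance gene score was high in tumour 4 (0.647).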

How the results depend on the processing

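The T cell, skeletal muscle and male-only settings and, for lists, sex and the surrogate variable were chosen after the data were seen, and the others before. The number of genes past the threshold, 0 in edgeR, was 158 higher and 251 lower in DESeq2, 40 and 154 in the classic exact test, 1 and 1 in limma-voom with quality weights, 4 and 73 with the skeletal muscle score as a term, and 2 and 0 in male tumours alone. Leaving out each tumour gave 0 to 1 genes higher and 0 lower, and the single gene came without control 1. Other normalizations, filters, the minimum fold, sex, the surrogate variable, the T cell score and runs of title numbers as a random block gave 0. The block setting allows for likeness of tumours within a run, with a fitted correlation of 0.0694. No run of title numbers held both genotypes, so it cannot compare genotypes within a run. Of the genes called by the classic exact test, 191 of 194 were also called by DESeq2. Why the tools differ was not tested on these tumours, although in simulated data DESeq2 made more false calls (51 against 2). Named genes kept their direction and side of the threshold in 2299 pairs of gene and setting, passed it in 86 (DESeq2, the classic exact test or the muscle term) and turned in 15. Most settings, the main one included, called 0 genes, so the side of the threshold was nearly fixed and shows no stability.

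The numbers of lists, 17 lower and 3 higher, became 0 and 0 with an estimated correlation and 1 and 0 with directional fry. With the muscle score as a term 1 list was higher, and 5 were with shared members left out. Leaving out each tumour gave 11 to 19 lists lower, with 11 without control 4, and 2 to 4 higher. The type I interferon, interferon-gamma and MHC class I lists passed in all settings but the estimated correlation and, for the latter pair, fry. Apart from fry, the settings they passed all used the preset correlation of 0.01. The correlation estimated in the data was 0.649, 0.887 and 0.913 for these lists in that order, so those settings do not test that assumption. With the T cell score as a term, medians turned for MHC class II (0.13), T cell (0.10, its own score) and dendritic (0.12) lists, and the NK and cytotoxic (-0.0623) and adipocyte (-0.27) lists turned in the test but not in the median. With the surrogate variable the medians of the MHC class II (0.0507) and dendritic (0.0669) lists were positive too, while the test kept its direction. The surrogate variable had a correlation of 0.866 with the T cell score, so these settings largely overlap. The adipocyte list also turned in the test without control 4, with a median from -1.87 to -0.27 over the tumours left out. Of the 20 lists, 17 were kept with sex as a term, 14 with the surrogate variable, 12 with the T cell score, 17 with the muscle score and 17 in male tumours. The causes were not tested. The number of lists with a score past the threshold was 0 in all 4 settings, which the design fixes or nearly fixes, so it shows no stability.

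Sex-linked genes turned with sex as a term (Ddx3y 0.34, Kdm5d 0.10, Uty 0.24), in male tumours alone (Xist -0.0656, Ddx3y 0.25, Kdm5d 0.0440, Uty 0.16), with the surrogate variable (Ddx3y 0.92, Kdm5d 0.43, Uty 0.65) and, for Ddx3y, with the T cell score (0.0392). The groups hold unequal shares of the sexes, and their differences in these genes are small next to the gap between the sexes. Mlph turned with the T cell score (-0.0822) and Ryr1 with the muscle score (-0.43). Over the tumours left out, Mlph ran from -0.0176 to 0.67 and Cdkn2a from -0.42 to 0.0393. The spread between tumours (biological coefficient of variation 0.416) limits what 6 and 4 tumours can resolve.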

Other observations

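The test of Y chromosome loss given here was chosen after the result was seen, and the rest of this part gives values.

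Several pigment genes, picked after their values were seen, had few or no counts in both genotypes, while 10 of the 22 members of the melanocyte list passed the expression filter. Tyr and Dct, which encode enzymes of melanin synthesis, had 0 counts in all 10 libraries, which allows up to 0.105 CPM in the shallowest library. Tyrp1 had 3 counts and Mlana 4 in all libraries together. Pmel stood at 0.713 ± 0.180 CPM (SD, n = 6) in Arf6Q67L tumours and 0.796 ± 0.135 CPM (SD, n = 4) in controls, and Sox10 at 0.582 ± 1.10 CPM and 0.411 ± 0.574 CPM. Mitf, the master regulator of the lineage, was at 17.0 ± 5.57 CPM and 16.6 ± 4.18 CPM, and Mlph at 10.2 and 7.19 CPM on average. Both were measured in bulk tissue, so their levels cannot be assigned to the tumour cells.

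Adhesion and guidance genes held members of both signs. Itga10, a collagen-binding integrin, was at 8.69 ± 2.30 CPM (SD, n = 6) against 4.34 ± 0.538 CPM (SD, n = 4), above all controls in 6 of 6 tumours, with an edgeR adjusted p of 0.233, and it was the 1 member of its list past the threshold adjusted over the list alone. Itgb4 of hemidesmosomes had a log2 fold change of -1.51 (SE 0.44). Sema3d was at 4.09 ± 2.96 CPM (SD, n = 6) against 0.686 ± 0.357 CPM (SD, n = 4), also in 6 of 6 tumours and the 1 guidance gene past the threshold adjusted over the list alone, while Sema6d (0.50, SE 0.18), Sema4d (-1.51, SE 0.55) and Slit2 (-0.998, SE 0.37) did not pass. Col6a2, a matrix collagen, was at 282 ± 104 CPM (SD, n = 6) against 106 ± 13.3 CPM (SD, n = 4), with an edgeR adjusted p of 0.233.

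The male Arf6Q67L tumour 2 had 9.62 CPM of Eif2s3y, against 74.3 to 99.8 CPM in the other male tumours, a log2 difference of -3.12 from their mean. Loss of the Y chromosome, or female cells, is argued against, since the median difference of Ddx3y, Kdm5d and Uty in that tumour was 0.55. A change limited to the Eif2s3y locus, or to its annotated sequence in that mouse, may account for it as a hypothesis that was not tested.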
